A study of Mus musculus with 9 samples.

How the data were processed

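The study measured RNA from E14 mouse embryonic stem cells in ES, 2iLIF and EPSCM medium, 3 libraries each. Per the labels, total RNA was extracted with a column kit and DNase treatment, and stranded libraries were made after selection of messenger RNA. The deposited file gives 1 FPKM value per gene and library (fragments scaled by transcript length and by library total), which the authors made with STAR and Cuffnorm against the mouse build mm9, per the submitters' processing notes; versions, the annotation, the scaling between libraries and the use of strand are not given in the sources used here. FPKM divides by transcript length and by library total, so a few abundant genes can shift all others, and values of low genes rest on few fragments. Every column of the file belongs to 1 sample and was used. Library sums ranged from 546636 to 600728 FPKM, and the 10 most abundant genes held 7.52% to 9.67% of a library.

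Before the data were examined, the tests, the gene lists, the rule for named genes and all alternatives were fixed, except those said to be chosen later. Values were taken as log2(FPKM + 1), and genes with at least 1 FPKM in at least 3 of 9 libraries were kept, 12330 of 24819. One limma model (limma 3.58.1 in R 4.3.3, mean per medium, empirical Bayes with a trend in the variance prior) was fitted over all 9 libraries, so that the comparisons share 1 estimate of the spread. The 3 comparisons were EPSCM against ES, EPSCM against 2iLIF and 2iLIF against ES, each with Benjamini-Hochberg adjustment over the tested genes. Calls needed an adjusted p under 0.05 and a log2 difference of at least 1 in size. Any difference among the media was tested with limma's moderated F statistic.

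Of 31 fixed gene lists, 28 had at least 5 tested genes and were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with an estimated correlation, where the lowest adjusted p was 0.150. Fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 23, 19 and 22 of 28 lists in the 3 comparisons, and all 28 when either direction counted. The named genes were, per comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between libraries, leaving out predicted, unnamed and small RNA genes; up to 4 called genes per list with the largest difference and a mean of at least 1 FPKM; and a fixed set of key genes whatever their values. Not every gene the rule takes is printed.

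Sets of genes called in 2 comparisons share libraries, so their overlap was set beside that of independent lists, which does not remove the sharing. The correlation and covariance of differences were set beside 100 simulations of 3 media with no difference; these held no overlapping calls, so they give no yardstick for the overlaps. On simulated data with the spread of the real 12330 genes and 200 changed genes, all 50 genes changed by 2 on the log2 scale were called in each of the 3 comparisons. Of 50 genes changed by 1.5, 50, 49 and 50 were called, and of 50 changed by exactly 1, the limit, 24, 25 and 28. At most 1 unchanged gene was called. A simulated list of 20 genes raised by 1 ranked ahead of all others in EPSCM against ES, and none of 50 unchanged lists was called. The simulated genes were independent, while the correlation estimated within real lists reached 0.636, for glycolysis. The simulation therefore gives no rate of false calls for the real lists.

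Libraries of a medium were checked for duplicates. With fragments estimated from the FPKM steps over genes with a single annotated transcript and more than 50 fragments in a pair, the chi-square statistic per degree of freedom was 1.62 to 2.96 between the 2 close libraries of a medium and 13.0 to 17.7 in pairs with the library that stands apart. Counting noise alone gives about 1. The highest value among the close pairs was that of ES. Whether close libraries are preparations of the same RNA is left open; they were kept as separate samples, and averaging them was added as an alternative. Covariates were tried: library numbers of at least 10, as planned, and the libraries that stand apart, chosen after seeing the data.

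Chromosome, gene order, transcript length and GC content came from RefSeq and GENCODE tables of GRCm38, matched by symbol. 24734 of 24819 symbols matched, 465 of them by a unique synonym. Because this assembly differs from mm9, no coordinates are printed, and the tables were used only for names and for which genes neighbour each other. A family of copies with near-identical sequence, such as histone, Tuba3 and MHC genes, may share reads, and their single values are uncertain.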

Results

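Mouse embryonic stem cells of the E14 line, a male line widely used in mouse genetics, were grown on gelatin in 3 media, and their polyadenylated RNA was sequenced. The first medium, called ES here, was serum medium with leukemia inhibitory factor (LIF). The second, 2iLIF, was serum-free N2B27 medium with LIF and the inhibitor pair known as 2i, which block MEK and GSK3. The third, EPSCM, was expanded potential stem cell medium, made to widen the developmental potential of the cells. Each medium had 3 libraries, so 9 in all, and the design text describes the cultures as stable in their medium. The labels do not say that the 3 libraries of a medium came from separate cultures, so every p-value below measures only the spread between these libraries, which may be technical.

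Values were FPKM for 24819 gene symbols, and 12330 genes reached 1 FPKM in at least 3 libraries and were tested. The table holds no read counts. The steps between its lowest values in genes with a single annotated transcript correspond to about 23.1e6 to 31.4e6 fragments per library, a rough estimate because the transcript lengths came from another annotation. At that depth 1 fragment in a transcript of 1 kb is worth 0.0318 to 0.0432 FPKM, so means under about 0.1 FPKM rest on very few fragments. Between 11155 and 11764 genes were at or above 1 FPKM in a library. Below, levels are mean FPKM ± SD (n = 3 libraries), and differences are on the log2(FPKM + 1) scale ± SE, which understates the change of genes with low values. A gene was called higher or lower at a limma adjusted p under 0.05 and a log2 difference of at least 1 in size.

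The first principal component of the tested genes held 48.9% of the variance and the second 41.3%, and together they separated the 3 media. The third held 6.46% and set 1 library of each medium apart from the others: ES replicate 1, 2iLIF replicate 1 and EPSCM replicate 2, which carry the library numbers 16, 18 and 19; replicates are numbered in the order of the sample labels. These are called the libraries that stand apart, and the rest the close libraries. Close libraries of a medium correlated across genes at r = 0.9959 to 0.9967, against 0.9855 to 0.9902 for pairs with a library that stands apart; genes are not independent replicates. Because each medium has exactly 1 of them, the split is balanced over the comparisons.

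**Figure D1:**
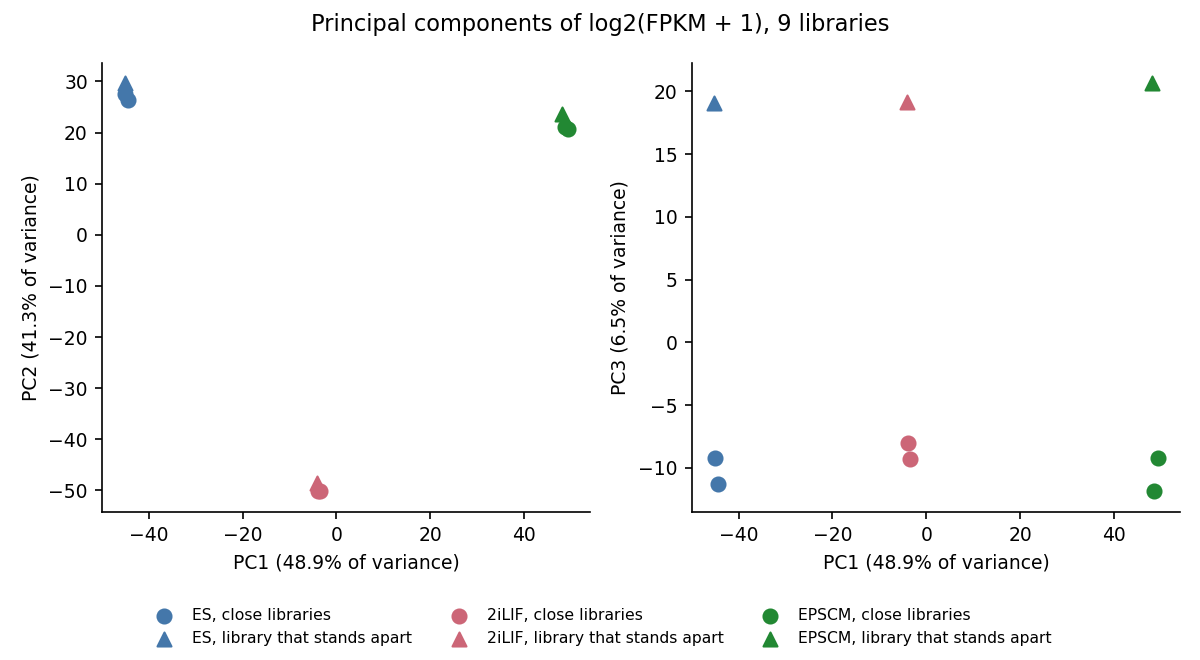
Scores of the 9 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), with the share of variance of each component on its axis. Colours mark the 3 media, and triangles mark the library of each medium that stands apart on the third component, which holds 6.46% of the variance.

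Dmrt1, the transcription factor named in the title of the series and known from testis and germ cell development, was measured first. It stood at 20.2 ± 0.560 FPKM in EPSCM, 8.13 ± 0.401 in ES and 5.18 ± 0.346 in 2iLIF. Its log2 difference was 1.22 ± 0.06 for EPSCM against ES (adjusted p = 3.06e-07) and 1.78 ± 0.06 for EPSCM against 2iLIF (adjusted p = 3.83e-08), and all 3 EPSCM libraries lay above the other 6. Between 2iLIF and ES the difference was -0.56 ± 0.06 (adjusted p = 5.08e-05), short of the fold limit. Of the 5 tested genes of the DMRT family, 3 were higher in EPSCM than in ES and none lower. Beside Dmrt1 these were Dmrtc2, at 5.76 ± 0.494 against 1.25 ± 0.0889 FPKM, and Dmrt3, at 2.07 ± 0.208 against 0.140 ± 0.0505. As a group the family did not pass in that comparison (camera adjusted p = 0.169, and adjusted p = 0.453 with an estimated correlation), except with no filter on low values (adjusted p = 0.0256). Against 2iLIF also 3 were higher, Dmrt1, Dmrtc2 and Dmrtb1, and the family passed (camera adjusted p = 0.00897, and adjusted p = 0.518 with an estimated correlation). Dmrtb1 was at 3.20 ± 0.141 FPKM in ES, above both 1.60 ± 0.117 in EPSCM and 0.111 ± 0.0301 in 2iLIF, and its call against 2iLIF was lost with quantile normalization, at 0.96.

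**Figure D2:**
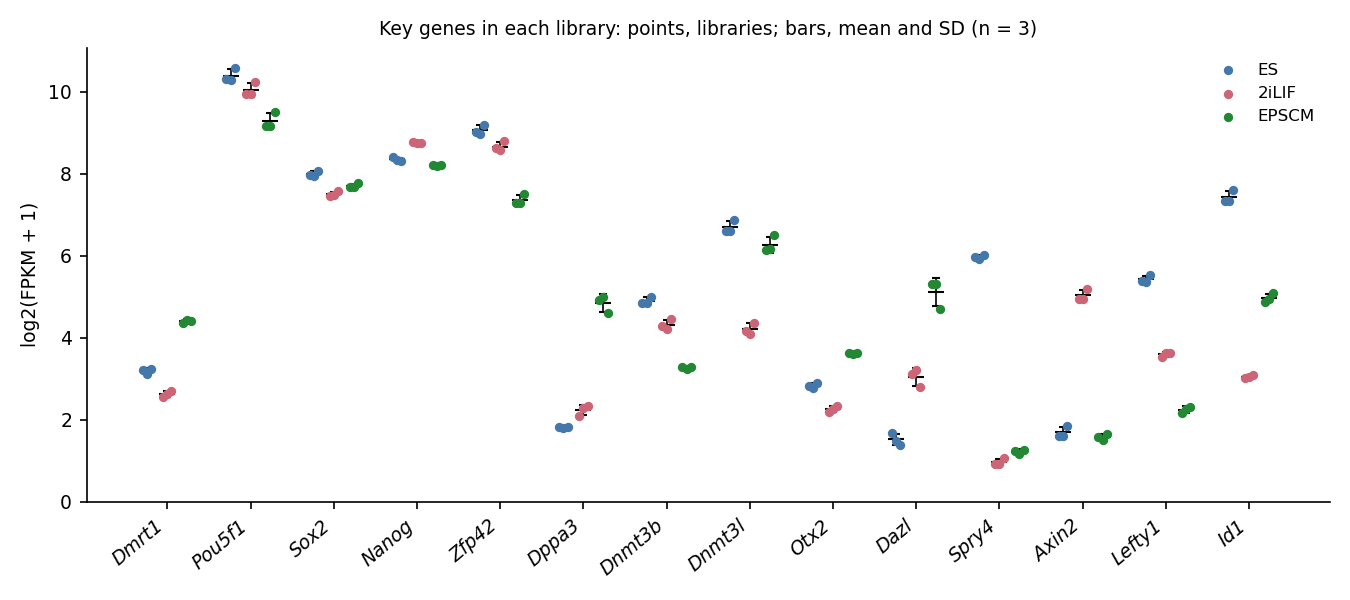
Level of 14 key genes in every library, as log2(FPKM + 1), with the mean and SD of the 3 libraries of each medium. Dmrt1, Dppa3 and Dazl lie highest in EPSCM, Spry4, Lefty1 and Id1 highest in ES, and Axin2 highest in 2iLIF.

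Cells in EPSCM were compared with cells in ES to ask how the expanded potential medium changes the transcriptome of cells otherwise kept in serum and LIF. Single genes with large differences come first. Stra8, which is needed for entry into meiosis, stood at 97.1 ± 1.13 FPKM in EPSCM and 2.67 ± 0.106 in ES, a log2 difference of 4.74 ± 0.08. Aqp3, a water and glycerol channel, rose to 411 ± 38.9 from 18.7 ± 0.943 FPKM. Myc fell to 0.343 ± 0.0855 from 37.3 ± 2.26 FPKM, a difference of -4.84 ± 0.07, and Inhbb, a subunit of activin and inhibin, by more (-4.95 ± 0.06). With limma, 2423 of 12330 genes were called, 1440 higher and 983 lower in EPSCM. The balance of rises and falls depends on the scaling: quantile normalization gave 1141 higher and 1162 lower, and scaling to the same median ratio 1322 higher and 1089 lower.

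The other genes with the largest rises were Tuba3b, Copz2, Crxos and Tinagl1, with differences of 4.95 ± 0.10, 4.49 ± 0.07, 4.29 ± 0.17 and 4.23 ± 0.08. Tuba3b has a near-identical copy, Tuba3a, and Crxos overlaps Crx on the other strand, so their single values are uncertain; whether strand was used in the counting is not given in the sources used here. The other largest falls were Spry4 at -4.75 ± 0.06, Enox1 at -4.71 ± 0.05, Fgf17 at -4.67 ± 0.10 and Trh at -4.55 ± 0.10.

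Of the core pluripotency list, 7 genes were lower and none higher among 12 tested (camera adjusted p = 0.00196, and adjusted p = 0.222 with an estimated correlation). Utf1, a chromatin-bound factor of undifferentiated cells, fell the most, at -4.19 ± 0.09. Dppa4 fell to 24.3 ± 0.787 from 106 ± 6.69 FPKM. Pou5f1 fell to 627 ± 88.4 from 1352 ± 162 (-1.11 ± 0.13), and Zfp42 to 163 ± 14.8 from 534 ± 46.0. Sox2 and Nanog, at -0.28 ± 0.06 and -0.14 ± 0.05, did not reach the fold limit. The naive pluripotency list had 2 higher and 7 lower among 21 tested (camera adjusted p = 0.00560, and adjusted p = 0.453 with an estimated correlation). Without the genes of chromosomes 1, 14 and Y only 3 were lower and 2 higher, and the call was lost (adjusted p = 0.0653). Gbx2 and Tdh, a threonine-catabolising enzyme abundant in mouse embryonic stem cells, had differences of -3.81 ± 0.08 and -3.40 ± 0.09. Klf4, Esrrb and Tfcp2l1 were at -0.47 ± 0.05, -0.51 ± 0.09 and -0.38 ± 0.11, none of them called. Against the direction of its list, Dppa3, a maternal factor that guards DNA methylation in the early embryo, rose to 27.9 ± 4.15 from 2.51 ± 0.0342 FPKM. The formative and primed list had 2 higher and 5 lower among 17 tested and did not pass (adjusted p = 0.903): Dnmt3b fell to 8.64 ± 0.222 from 28.7 ± 2.01 FPKM, and Zic2 rose to 17.0 ± 0.534 from 2.72 ± 0.220. Otx2, at 0.79 ± 0.06, and Dnmt3l, at -0.43 ± 0.12, were short of the fold limit. Prdm14 was at 0.36 ± 0.06.

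The germline and meiosis list had 16 higher and 1 lower among 29 tested (camera adjusted p = 0.0335, and adjusted p = 0.453 with an estimated correlation). Beside Stra8, Dazl, an RNA-binding protein of germ cells, rose to 34.3 ± 7.88 FPKM from 1.87 ± 0.294 and Tuba3a to 166 ± 18.3 from 16.2 ± 1.06. Slc25a31, the ADP/ATP carrier of testis, differed by 2.90 ± 0.08. Sycp3 was at 0.38 ± 0.11 and was not called. The group call was lost at an adjusted p of 0.0616 with the libraries that stand apart as a covariate, at 0.0553 with libraries scaled to the same sum, at 0.0522 with array weights and at 0.0937 over genes with a mean of at least 5 FPKM. Over the other settings at the preset correlation it ranged from 0.0108 to 0.0937. Only 4 of the 22 genes of the 2-cell-like list in the table were tested, and 3 were lower in EPSCM. Zscan4c, a marker of 2-cell-like cells, was at 0.291 ± 0.119 FPKM against 1.71 ± 0.580 (-1.05 ± 0.15). Its call was lost without ES replicate 2 (-0.93), without ES replicate 3 (-0.98) or without EPSCM replicate 2 (-0.99). It was also lost with library numbers of at least 10 as a covariate (-0.97) and with the close libraries averaged (-0.99). Zfp352 stayed under 1 FPKM in all 3 media.

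The list of targets and feedback regulators of ERK signalling had 2 higher and 11 lower among 18 tested (camera adjusted p = 2.51e-04, and adjusted p = 0.453 with an estimated correlation). Spry4 dropped to 1.33 ± 0.0893 FPKM from 61.5 ± 2.07, Dusp6 to 3.31 ± 0.482 from 37.8 ± 3.89 and Spry2 to 15.1 ± 0.400 from 124 ± 2.21. Genes induced by LIF through STAT3 were lower in 6 of 16 and higher in none (camera adjusted p = 0.0159, and adjusted p = 0.453 with an estimated correlation), among them Junb at -1.60 ± 0.11 and Klf5 at -1.45 ± 0.06. BMP and ID genes were lower in 4 of 13 without passing as a list (adjusted p = 0.492), led by Id3, which fell to 1.86 ± 0.187 FPKM from 35.8 ± 4.33, and Id1, which fell to 30.3 ± 2.36 from 172 ± 19.7. The NODAL antagonists Lefty1 and Lefty2 were lower, at 3.73 ± 0.269 from 41.9 ± 2.56 and 3.87 ± 0.123 from 48.6 ± 3.80 FPKM, and the list as a whole had 4 higher and 4 lower (adjusted p = 0.903). WNT targets did not pass (adjusted p = 0.672), and Axin2 was at -0.10 ± 0.10.

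Glycolysis had 9 higher and 0 lower among 20 tested (camera adjusted p = 0.0257, and adjusted p = 0.851 with an estimated correlation), with the glucose transporter Slc2a3 at 1434 ± 3.75 FPKM against 365 ± 5.41 and the isomerase Gpi1 at 919 ± 133 against 222 ± 21.9. Fatty acid synthesis had 6 higher and 1 lower among 15 tested (camera adjusted p = 0.0190, and adjusted p = 0.293 with an estimated correlation): Me1 and Scd1 rose, at 2.23 ± 0.07 and 1.67 ± 0.06. Cholesterol biosynthesis had 7 higher and 0 lower among 24 tested (camera adjusted p = 0.0466, and adjusted p = 0.293 with an estimated correlation), with Msmo1 at 1.69 ± 0.13 and Insig1, a sterol sensor, at 1.58 ± 0.07; the call was lost with libraries scaled to the same sum (adjusted p = 0.0612) and with the close libraries averaged (0.0550). No gene of oxidative phosphorylation was called among 24 tested, and the list was lower by a small amount (median -0.13, camera adjusted p = 0.0490, and adjusted p = 0.453 with an estimated correlation), a call that 10 of 24 other settings of that test ended (adjusted p = 0.990 after quantile normalization). The amino acid stress list had 2 higher and 7 lower among 22 tested (camera adjusted p = 0.00560, and adjusted p = 0.455 with an estimated correlation): its regulator Atf4 fell to 75.7 ± 2.27 from 237 ± 2.53 FPKM, while Ddit3 rose to 59.3 ± 6.06 from 11.5 ± 1.42. The p53 target list had 2 higher and 6 lower among 19 tested (camera adjusted p = 0.0159, and adjusted p = 0.293 with an estimated correlation), with Perp at -2.77 ± 0.08; without those chromosomes 3 were lower.

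Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, were lower in 33 of 41 tested genes and higher in none (camera adjusted p = 2.14e-08, and adjusted p = 0.453 with an estimated correlation). The name pattern behind this list also takes 6 H2af variant histone genes, which hold most of its FPKM. Without them, an alternative chosen after seeing the data, 32 of 35 were lower and none higher (camera adjusted p = 8.88e-09, and adjusted p = 0.453 with an estimated correlation). The single copies share sequence, and the 35 genes summed to 23.4 to 36.2 FPKM in the EPSCM libraries against 123 to 180.0 in the ES libraries. Cell cycle genes did not pass as a list (adjusted p = 0.184), but Ccnd2 fell to 0.123 ± 0.0261 from 15.1 ± 0.249 FPKM, Ccne1 to 42.4 ± 1.68 from 165 ± 5.26, and the cell cycle inhibitor Cdkn2a rose to 45.8 ± 5.63 from 3.74 ± 0.731. Ribosomal protein genes had no called member among 84.

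Lists of other cell types did not pass. The trophoblast list had 3 higher and 2 lower among 19 tested (adjusted p = 0.903), with Esx1 higher at 10.5 ± 1.72 against 0.599 ± 0.318 FPKM, and Elf5 and Gata3 under 1 FPKM in all 3 media. Cdx2 was at 0.0411 ± 0.0229 against 0.109 ± 0.0309. The primitive endoderm list had 5 higher and 1 lower among 17 tested (adjusted p = 0.454): Col4a1 was at 27.1 ± 1.09 against 5.79 ± 0.223, Gata6 at 3.17 ± 0.245 against 0.675 ± 0.0520, and Sox17 under 1 FPKM in all 3. The mesoderm list had 4 higher and none lower among 8 (adjusted p = 0.0722), with T at 0.412 ± 0.118 against 0.190 ± 0.0187. The fibroblast list had 3 higher and 1 lower among 10 (adjusted p = 0.812). Neural, YAP and cytoskeleton, imprinted, DNA methylation and stress lists had adjusted p-values of 0.966, 0.903, 0.907, 0.903 and 0.961. Single imprinted genes still changed strongly, such as Cdkn1c at -3.66 ± 0.10, Grb10 at -3.47 ± 0.05 and Plagl1 at 2.78 ± 0.10. HOX genes had 4 tested members, 2 of them higher.

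In this comparison the genes of chromosome 1 had a median difference of -0.29, against 0.11 over the other autosomes, and runs of chromosome 14 genes moved together; the Y-linked genes were lower in ES. Inhbb, Gbx2, Lefty1, Lefty2 and Tfcp2l1 lie on chromosome 1, and Enox1, Fgf17, Tdh, Spry2, Klf5, Zic2 and Otx2 on chromosome 14, by the RefSeq table of GRCm38. Without the genes of chromosomes 1, 14 and Y, an alternative chosen after seeing the data, 1351 genes were higher and 799 lower, and 5 group calls were lost: oxidative phosphorylation (adjusted p = 0.144), naive pluripotency (0.0653), cholesterol biosynthesis (0.0994), p53 targets (0.0845) and STAT3 targets (0.0845). The ranges of the last 4 over the other settings at the preset correlation were from 0.00106 to 0.0653, from 0.0149 to 0.0994, from 0.00394 to 0.0845 and from 0.00486 to 0.0845. Within the close libraries alone 1452 genes were higher and 971 lower, and the libraries that stand apart are 1 per medium, too few for a test. Adjusted over the list alone, no count of the 28 tested lists changed in any of the 3 comparisons. No list call in any comparison held with an estimated correlation. That correlation was estimated without the libraries that stand apart as a covariate, so the shift they share may enter it. The median and the test differed in sign for 7 lists here, none of them passing.

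EPSCM was next compared with 2iLIF, the medium that holds cells in the naive, or ground, state, to ask where the transcriptomes part. Single genes again come first. Ndufa4l2, a mitochondrial protein induced by hypoxia-inducible factor, stood at 104 ± 12.5 FPKM in EPSCM and 1.12 ± 0.248 in 2iLIF (5.63 ± 0.12). Igfbp4, which binds insulin-like growth factors, was at 61.2 ± 4.52 against 0.353 ± 0.0861 FPKM. Sp5, a direct WNT target, was at 0.369 ± 0.0631 against 70.3 ± 6.34 (-5.70 ± 0.07). With limma 1979 genes were called, 1250 higher and 729 lower in EPSCM, so that 63.2% were higher; after quantile normalization that share was 52.8%, with 1010 higher and 902 lower.

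Other large rises were Stra8 at 4.67 ± 0.08, Tuba3b at 4.31 ± 0.10 and Loxl2, a lysyl oxidase, at 4.31 ± 0.05. The other largest falls were Nkx1-2 at -4.87 ± 0.05, Tnni1 at -4.60 ± 0.10, Trpm1 at -4.51 ± 0.08, Accsl at -4.05 ± 0.06 and Dmgdh at -4.04 ± 0.08. Canonical WNT targets had 2 higher and 6 lower among 15 tested (camera adjusted p = 0.00479, and adjusted p = 0.518 with an estimated correlation): Axin2 fell to 2.00 ± 0.154 FPKM from 31.8 ± 3.24, T to 0.412 ± 0.118 from 12.7 ± 0.854, and Cdx1 to 8.12 ± 0.512 from 83.7 ± 6.39. Cdx2, which is a WNT target and a trophoblast factor, was at 0.0411 ± 0.0229 against 2.85 ± 0.118 FPKM (-1.89 ± 0.05).

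The naive pluripotency list had 2 higher and 9 lower among 21 tested (camera adjusted p = 3.23e-04, and adjusted p = 0.518 with an estimated correlation). Tdh fell to 34.9 ± 3.02 from 449 ± 32.4 FPKM, Zfp57, a keeper of imprints, to 67.6 ± 4.14 from 319.9 ± 2.68, Tfcp2l1 to 74.3 ± 6.76 from 231 ± 22.6 and Klf4 to 61.5 ± 0.927 from 143 ± 4.67. Esrrb, Nanog and Prdm14 were at -0.73 ± 0.09, -0.55 ± 0.05 and -0.52 ± 0.06, not called. Dppa3 again went the other way, at 2.61 ± 0.11. The formative and primed list had 8 higher and 1 lower among 17 tested (camera adjusted p = 3.23e-04, and adjusted p = 0.518 with an estimated correlation): the methyltransferase Dnmt3a rose to 12.6 ± 0.878 from 1.85 ± 0.0953 FPKM, Fgf15 to 4.24 ± 0.154 from 0.151 ± 0.0713, Sox3 to 2.58 ± 0.115 from 0.170 ± 0.0177 and Otx2 to 11.3 ± 0.105 from 3.79 ± 0.251. Dnmt3b was the 1 member called lower, at -1.05 ± 0.07, and without 2iLIF replicate 1 it missed the fold limit at -0.98. Dnmt3l rose to 76.6 ± 11.2 from 17.5 ± 1.83. Core pluripotency genes did not pass (adjusted p = 0.456); Zfp42 was at -1.30 ± 0.09, Pou5f1 at -0.76 ± 0.13 and Sox2 at 0.21 ± 0.06.

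Germline and meiosis genes had 17 higher and 2 lower among 29 tested (camera adjusted p = 0.00432, and adjusted p = 0.518 with an estimated correlation), with Sohlh2 at 99.7 ± 5.08 against 14.7 ± 1.57 FPKM, Mael at 10.3 ± 2.62 against 0.813 ± 0.179 and Dazl at 34.3 ± 7.88 against 7.28 ± 1.19. Over genes with a mean of at least 5 FPKM that group call was lost (adjusted p = 0.570; over the other settings at the preset correlation it ranged from 7.63e-04 to 0.570). Glycolysis had 11 higher and 0 lower among 20 tested (camera adjusted p = 6.78e-07, and adjusted p = 0.572 with an estimated correlation): the lactate exporter Slc16a3 rose to 166 ± 16.6 from 16.1 ± 1.78 and Pgk1 to 945 ± 19.3 from 237 ± 7.49, and Slc2a1 differed by 2.32 ± 0.11. Mesenchymal genes of the fibroblast list had 3 higher and 0 lower among 10 tested (camera adjusted p = 0.00432, and adjusted p = 0.518 with an estimated correlation), with Thy1 at 6.02 ± 0.762 against 0.410 ± 0.0412 FPKM and Mmp2 at 8.43 ± 0.916 against 0.921 ± 0.0827; both are also expressed in ES, at 14.4 ± 1.12 and 8.49 ± 0.834. With no filter on low values that list had an adjusted p of 0.0631, in a range over the settings at the preset correlation from 0.00302 to 0.0631.

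ERK feedback targets did not separate EPSCM from 2iLIF as a list (adjusted p = 0.708), and Spry4 was low in both, at 1.33 ± 0.0893 and 0.957 ± 0.112 FPKM. Single members differed: Myc was at 0.343 ± 0.0855 against 4.48 ± 0.197, and Ier3 at 42.2 ± 7.04 against 3.51 ± 0.583. The BMP and ID list, with an adjusted p of 0.913, split: Id3 was lower at -3.73 ± 0.10 and Id4 at -2.62 ± 0.09, Id1 higher at 1.91 ± 0.09 and Id2 higher at 3.47 ± 0.17. Lefty1 fell to 3.73 ± 0.269 from 11.1 ± 0.447 FPKM and Lefty2 to 3.87 ± 0.123 from 45.2 ± 0.770. The metallothioneins Mt1 and Mt2 were lower, at -1.85 ± 0.11 and -2.41 ± 0.10, and Socs3, the feedback inhibitor of STAT3, was higher at 1.92 ± 0.09, in a list that did not pass (adjusted p = 0.434). Cholesterol, fatty acid, oxidative phosphorylation, amino acid stress, p53, cell cycle and histone lists did not pass, with adjusted p-values of 0.913, 0.721, 0.923, 0.434, 0.434, 0.913 and 0.269; after quantile normalization the histone list did (adjusted p = 0.0465). Trophoblast and primitive endoderm lists did not pass either (adjusted p = 0.913 and 0.434); Gata6 was higher at 1.73 ± 0.06 and Krt8 lower at -2.77 ± 0.10. Within the close libraries alone 1238 genes were higher and 730 lower. Tnni1, Tfcp2l1, Mael, Lefty1 and Lefty2 lie on chromosome 1, whose genes had a median difference of -0.05 here, and Loxl2, Tdh and Otx2 on chromosome 14.

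2iLIF was compared with ES to show, within the same experiment, the better known step from serum to the ground state. Genes that respond to WNT and ERK signalling were among the largest single changes. Sp5 went to 70.3 ± 6.34 FPKM from 1.15 ± 0.0431 (5.05 ± 0.07), Cdx1 to 83.7 ± 6.39 from 1.84 ± 0.237, and Axin2 to 31.8 ± 3.24 from 2.23 ± 0.318. Spry4 fell to 0.957 ± 0.112 FPKM from 61.5 ± 2.07 (-5.00 ± 0.06), and Id1 to 7.30 ± 0.244 from 172 ± 19.7. With limma 1817 genes were called, 939 higher and 878 lower in 2iLIF. Quantile normalization gave 854 higher and 871 lower and scaling to the same median ratio 864 higher and 969 lower, while scaling to the same sum gave 1017 higher and 821 lower, so the direction of the excess depends on the scaling. With pseudocounts of 0.1 and 0.01 the count was 2738 and 2863, since a smaller pseudocount widens the differences of genes with low values.

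Canonical WNT targets had 7 higher and 2 lower among 15 tested (camera adjusted p = 0.00485, and adjusted p = 0.486 with an estimated correlation), and mesoderm and streak genes, which share T and Cdx1 with them, had 3 higher and 1 lower among 8 tested (camera adjusted p = 0.0183, and adjusted p = 0.486 with an estimated correlation). T rose to 12.7 ± 0.854 FPKM from 0.190 ± 0.0187, Gsc to 6.28 ± 0.834 from 0.530 ± 0.147 and Cdx2 to 2.85 ± 0.118 from 0.109 ± 0.0309. With no filter on low values the mesoderm list had an adjusted p of 0.0664, in a range over the settings at the preset correlation from 0.0130 to 0.0664. ERK feedback targets had 1 higher and 9 lower among 18 tested (camera adjusted p = 1.52e-05, and adjusted p = 0.486 with an estimated correlation): Dusp6 fell to 4.35 ± 0.130 from 37.8 ± 3.89, Myc to 4.48 ± 0.197 from 37.3 ± 2.26 and Etv4 to 13.1 ± 0.940 from 82.2 ± 7.84 FPKM. The other largest rises were Crxos (5.91 ± 0.17), Ly6a (5.39 ± 0.09), Trpm1 (4.94 ± 0.08) and S100a1 (4.94 ± 0.15), and the other largest falls Inhbb (-5.08 ± 0.06), Cdkn1c (-4.53 ± 0.10), Slc39a14 (-4.25 ± 0.06) and Utf1 (-4.20 ± 0.09).

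The formative and primed list had 1 higher and 7 lower among 17 tested (camera adjusted p = 0.00118, and adjusted p = 0.404 with an estimated correlation). Dnmt3a fell to 1.85 ± 0.0953 from 13.4 ± 1.03 FPKM, Fgf15 to 0.151 ± 0.0713 from 11.1 ± 0.879 and Pou3f1 to 0.191 ± 0.0458 from 5.22 ± 0.185. Dnmt3l, a cofactor of DNA methylation outside that list, was lower at -2.49 ± 0.12, and Dnmt3b, at -0.57 ± 0.07, and Otx2, at -0.57 ± 0.06, were short of the fold limit. Core pluripotency genes had 0 higher and 3 lower among 12 tested (camera adjusted p = 0.00655, and adjusted p = 0.150 with an estimated correlation): Utf1 was lower by the most, and the RNA-binding protein Lin28a fell to 20.8 ± 2.09 from 95.5 ± 11.2. Pou5f1, Sox2, Nanog and Zfp42 were at -0.35 ± 0.13, -0.49 ± 0.06, 0.41 ± 0.05 and -0.40 ± 0.09. The naive list did not pass (adjusted p = 0.399). Tfcp2l1 rose to 231 ± 22.6 from 97.3 ± 11.1, Bmp4 fell to 9.54 ± 0.904 from 54.6 ± 6.49, and Klf4, Prdm14, Esrrb and Dppa3 were at 0.73 ± 0.05, 0.88 ± 0.06, 0.23 ± 0.09 and 0.42 ± 0.11, under the fold limit.

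Fatty acid synthesis had 7 higher and 0 lower among 15 tested (camera adjusted p = 0.00485, and adjusted p = 0.150 with an estimated correlation), with the desaturases Scd1 and Scd2 at 2.50 ± 0.06 and 1.84 ± 0.04. Cholesterol biosynthesis had 4 higher and 0 lower among 24 tested (camera adjusted p = 0.00286, and adjusted p = 0.150 with an estimated correlation), with Insig1 at 1.25 ± 0.07. Glycolysis had 0 higher and 5 lower among 20 tested (camera adjusted p = 0.0135, and adjusted p = 0.850 with an estimated correlation): Pdk1 fell to 8.92 ± 0.484 from 43.2 ± 2.30 FPKM, and Slc2a1 was at -2.04 ± 0.11. The amino acid stress list had 1 higher and 3 lower among 22 tested (camera adjusted p = 0.0426, and adjusted p = 0.770 with an estimated correlation); Phgdh fell to 48.4 ± 4.55 from 147 ± 15.4, Asns rose to 427 ± 63.4 from 157 ± 24.9, and the call was lost without ES replicate 1 (adjusted p = 0.0653), without 2iLIF replicate 2 (0.0572), with the close libraries averaged (0.0514) and with quantile normalization (0.166). The p53 target list had 1 higher and 5 lower among 19 tested (camera adjusted p = 0.0207, and adjusted p = 0.386 with an estimated correlation): Pmaip1 was lower at -2.79 ± 0.07, while Cdkn1a rose to 160.2 ± 12.5 from 43.3 ± 3.82. Histone genes were lower in 27 of 41 and higher in none (camera adjusted p = 7.53e-07, and adjusted p = 0.486 with an estimated correlation), and 24 were lower within the close libraries alone. Without the 6 H2af genes 27 of 35 were lower (camera adjusted p = 2.82e-07, and adjusted p = 0.486 with an estimated correlation), with sums of 41.2 to 54.7 FPKM in the 2iLIF libraries. Over genes with a mean of at least 5 FPKM the histone list had an adjusted p of 0.0544, in a range over the settings at the preset correlation from 2.53e-10 to 0.0544.

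Oxidative phosphorylation lay near the limit in this comparison, lower with no called gene (median -0.21, camera adjusted p = 0.0519, and adjusted p = 0.495 with an estimated correlation), and 11 of 24 other settings at the preset correlation passed it, with a range from 0.00239 to 0.601. The lists that follow did not pass. Germline and meiosis genes had 4 higher and 7 lower among 29 tested (adjusted p = 0.704), with Kit at 1.60 ± 0.05, Dazl at 1.52 ± 0.18, Piwil2 at -1.59 ± 0.06 and Ddx4 at -1.56 ± 0.25. STAT3 targets had 3 higher and 7 lower among 16 tested (adjusted p = 0.466), with Socs3 lower at -2.30 ± 0.09 and Mt1 higher at 2.01 ± 0.11. Trophoblast, primitive endoderm, neural, fibroblast, YAP and cytoskeleton, imprinted and cell cycle lists had adjusted p-values of 0.649, 0.962, 0.587, 0.403, 0.286, 0.535 and 0.202. Of the 4 tested HOX genes 3 were higher, among them Hoxb9 at 5.77 ± 0.764 against 0.954 ± 0.0308 FPKM. Ccnd2 and Ccne1 were lower and Cdkn2a higher than in ES, at -3.84 ± 0.05, -2.14 ± 0.05 and 3.12 ± 0.14. The genes of chromosome 1 had a median difference of -0.28, against 0.03 over the other autosomes. Inhbb, which fell, and Tfcp2l1, which rose, lie on chromosome 1. Slc39a14, Bmp4, Otx2 and Piwil2 lie on chromosome 14. Without the genes of chromosomes 1, 14 and Y, 877 were higher and 740 lower, and the p53 list had an adjusted p of 0.0915, in a range over the settings at the preset correlation from 0.00918 to 0.0915. Within the close libraries alone 938 genes were higher and 879 lower.

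**Figure D3:**
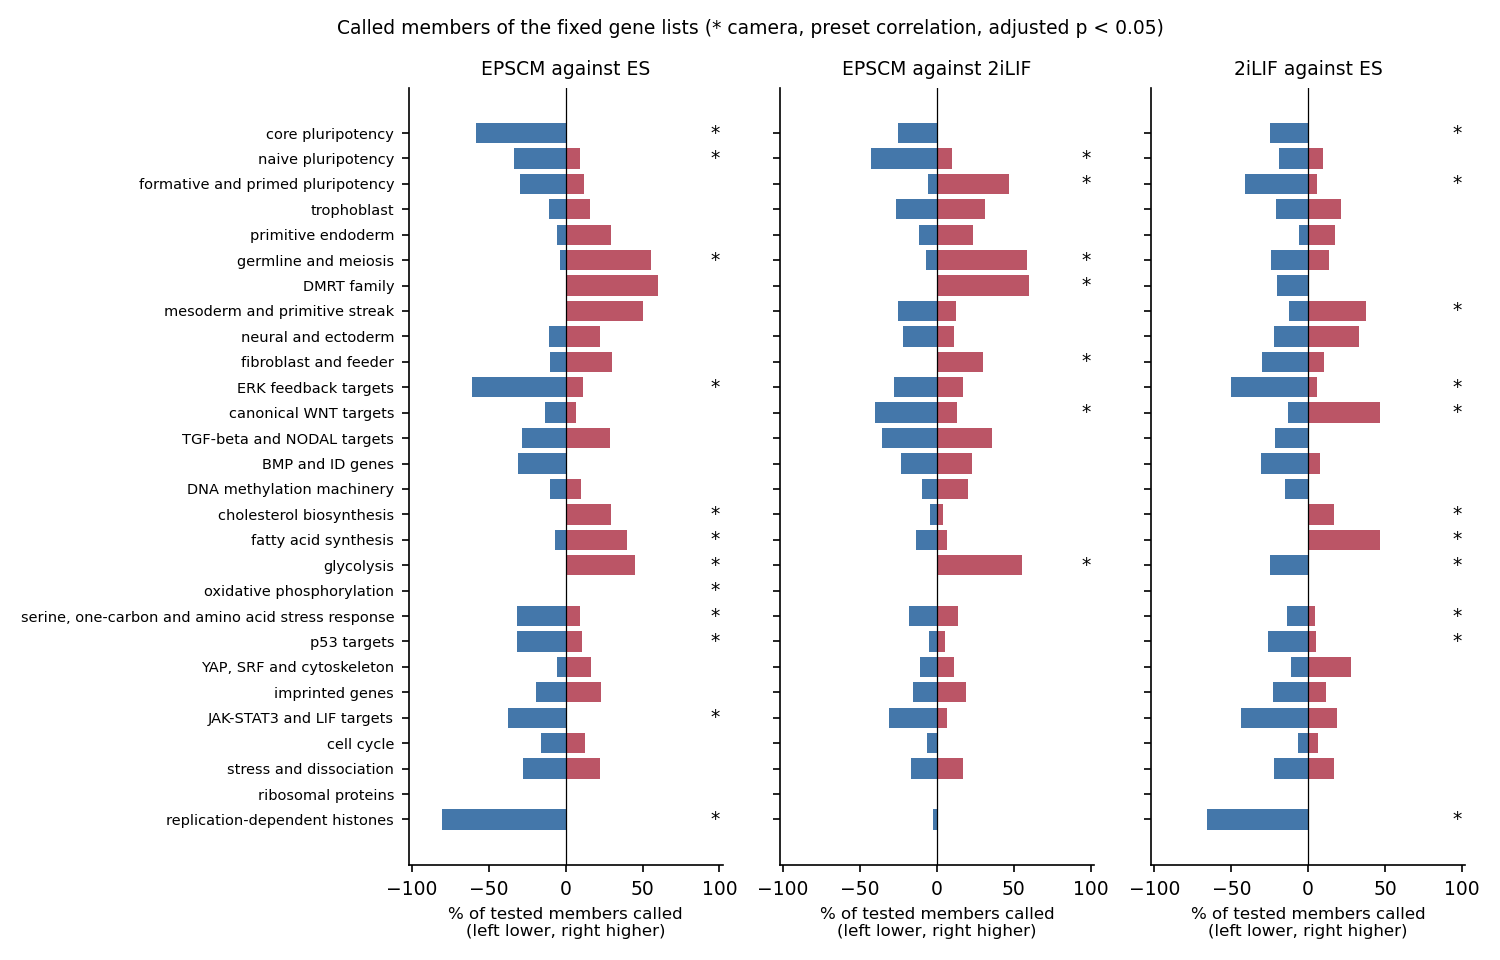
Share of the tested members of each fixed gene list called lower (blue, to the left) or higher (red, to the right), in percent, in the 3 comparisons; a star marks lists with a camera adjusted p under 0.05 at the preset correlation, none of which held with an estimated correlation. Histone genes extend furthest to the left in both comparisons against ES, with 33 and 27 of 41 members lower.

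Across the 3 media, 10544 of 12330 genes (85.5%) differed in limma's test of any difference. Genes set apart in EPSCM were those called against both other media. 603 genes were higher in EPSCM than in both, where independent lists of these sizes would share 146. 236 were lower than in both, against 58.1. The EPSCM libraries serve in both comparisons, so part of this excess may come from them. Quantile normalization gave 484 higher and 325 lower, and a mean of at least 5 FPKM 255 and 198, so the balance depends on these choices. By the smaller of their differences, Stra8, Tuba3b, Igfbp4, Pdpn and Col9a2 led the genes higher in EPSCM, and Id3, Tdh, Msc, Lefty2 and Slc7a3 those lower. Pdpn, a mucin-type membrane protein, was at 35.9 ± 5.84 FPKM against 2.47 ± 0.158 in ES and 3.05 ± 0.534 in 2iLIF, and Slc7a3, a carrier of basic amino acids, at 7.68 ± 0.184 against 95.2 ± 5.40 and 71.5 ± 2.46. Pdpn, Col9a2, Msc and Slc7a3 lie outside the rule for named genes and were picked after their values were seen. By count per list, germline and meiosis had the most genes higher in EPSCM than in both, 13 of 29, followed by glycolysis with 6 of 20, and ERK feedback targets the most lower than in both, 5 of 18, though 4 of 14 TGF-beta and NODAL targets is a larger share.

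EPSCM and 2iLIF were also compared through their shared reference, ES. 407 genes were higher than ES in both media, against 109.7 for independent lists, 381 were lower in both, against 70.0, and 55 were called in opposite directions, against 177. Without the genes of chromosomes 1, 14 and Y, 679 genes were called the same way in both, against 788 with them. Spry4, Utf1, Inhbb, Ccnd2 and Cdkn1c fell in both, Crxos, Me1 and Cdkn2a rose in both, and 25 of 41 histone genes fell in both. The differences correlated across genes at r = 0.525 (Spearman's rho 0.506), and a simulation of media with no difference gave r = 0.493 from the shared ES libraries alone. The covariance was 0.348, against a simulated 0.00917, a difference of 0.339. This difference is beyond what the spread between the shared libraries gave in the simulation. The 3 shared ES libraries cannot be split into parts of at least 2. A trait common to all 3 of them may therefore still add to the covariance and to the shared calls.

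**Figure D4:**
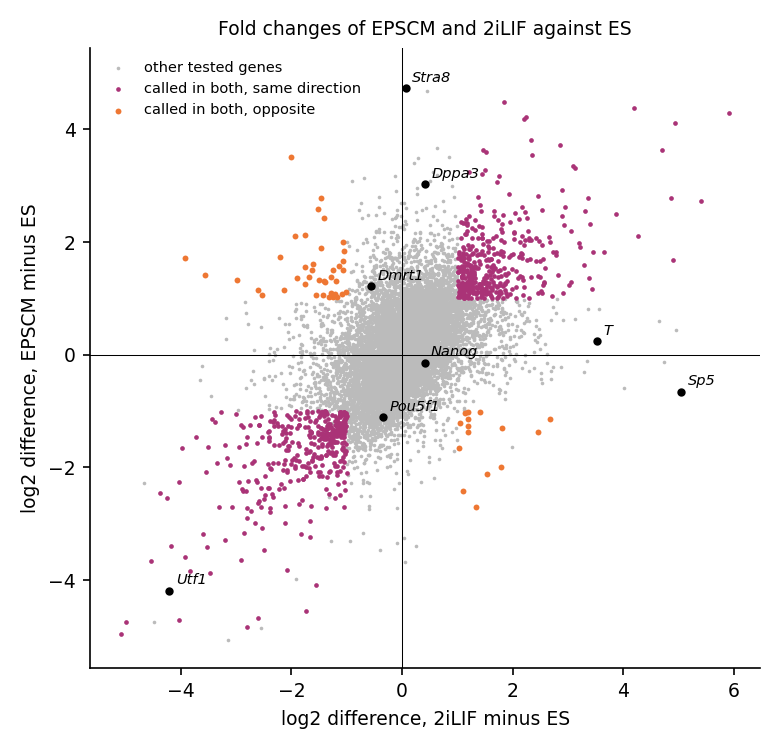
Each point is 1 of 12330 tested genes, placed by its log2 difference for 2iLIF minus ES (horizontal) and EPSCM minus ES (vertical), on the log2(FPKM + 1) scale; colours mark genes called in both comparisons in the same or in opposite directions. Utf1 lies low in both, Sp5 and T move in 2iLIF, and Stra8 and Dppa3 rise in EPSCM.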

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

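The alternatives with the libraries that stand apart, with averaged close libraries, without chromosomes 1, 14 and Y and with the shorter histone list were chosen after seeing the data; all others were planned. Over genes with a mean of at least 5 FPKM, fewer genes were tested and 1532, 1025 and 1055 were called in EPSCM against ES, EPSCM against 2iLIF and 2iLIF against ES, with 255 higher in EPSCM than in both and 514 shared by the comparisons against ES. With pseudocounts of 0.1 and 0.01 there were 2738 and 2863 called genes in 2iLIF against ES, 923 and 955 higher in EPSCM than in both, 439 and 485 lower than in both, and 1312 and 1381 shared, since smaller pseudocounts widen the differences of low genes. With no fold limit 9015, 8381 and 8265 genes passed. Leaving out each library in turn gave 2405 to 2492, 1975 to 2017 and 1808 to 1895 called genes, 10158 to 10663 that differed among the media, 598 to 626 and 235 to 257 higher and lower in EPSCM than in both, and 761 to 808 shared. All other alternatives stayed within 1.5 times these counts. Of 349 named gene results, 18 changed their side of the limits in at least 1 alternative and none changed direction. For the lists, 30 calls were lost with an estimated correlation. DNA methylation genes, not called in EPSCM against 2iLIF by camera and lower there, passed fry in the other direction (adjusted p = 0.00167); the tests ask different questions, and the cause was not tested further. The table holds no counts, so depth limits mainly the genes under about 1 FPKM, where the pseudocount sets the size of a difference. No paired analysis was possible because the library numbers in the labels are all different, so no number is shared between media.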

Other observations

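The lists, alternatives and tests of explanations in this part were chosen after the data were seen, except the test of transcript GC content in the libraries that stand apart and that of expression level, length and GC content on chromosomes 1 and 14, which were written before their results, and the counts over other splits, which the design asked for. Genes that hypoxia-inducible factor induces tended to be highest in EPSCM and lowest in 2iLIF, though some of them went the other way. In a list of 36 such genes without the glycolysis genes, 34 were tested: 18 were higher in EPSCM than in ES and none lower, 23 were higher in EPSCM than in 2iLIF and none lower, and 14 were lower in 2iLIF than in ES and 1 higher. With camera the adjusted p was 1.45e-05, 8.84e-12 and 1.79e-07 in these comparisons, and 0.0283, 0.01 and 0.0184 with an estimated correlation, adjusted over 6 tests. Adrenomedullin (Adm) was at 14.5 ± 2.14 FPKM in EPSCM, 0.764 ± 0.0977 in ES and 0.0905 ± 0.0243 in 2iLIF, Bnip3, a mitophagy receptor, at 160.1 ± 28.7, 35.6 ± 5.31 and 9.89 ± 2.14, and the collagen hydroxylase P4ha2 at 37.2 ± 2.86, 9.28 ± 0.964 and 2.69 ± 0.148. Egln3 was alike in EPSCM and ES, at 18.1 ± 1.60 and 20.9 ± 1.49, and 0.785 ± 0.0876 in 2iLIF. Kdm3a was the member called higher in 2iLIF, at 1.42 ± 0.16 against ES. Short of the fold limit, Rcor2, Stc2 and Angptl4 were lower in EPSCM than in ES, at -0.91 ± 0.10, -0.79 ± 0.11 and -0.33 ± 0.13. Pfkfb4, like Kdm3a, was highest in 2iLIF. The list was written with its leading genes in view, so its p-values describe a picked group.

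A list of antigen presentation genes was written after H2 genes had been seen among those highest in EPSCM, so its p-values too describe a picked group. Of its 24 genes, 17 were tested: 10 were higher and 1 lower against ES (camera adjusted p = 3.10e-04, and adjusted p = 0.169 with an estimated correlation), 14 higher and none lower against 2iLIF (2.28e-05 and 0.137), and 2 higher and 6 lower in 2iLIF against ES (0.0321 and 0.358). At the preset correlation the value for 2iLIF against ES was 0.0558 with the libraries that stand apart as a covariate. H2-K1 was at 45.4 ± 4.82 FPKM in EPSCM, 15.3 ± 1.58 in ES and 4.30 ± 0.423 in 2iLIF, and the class II gene H2-Ab1 at 17.1 ± 1.80, 1.14 ± 0.103 and 0.144 ± 0.0315. B2m, the light chain of class I, was at 96.7 ± 8.86 in EPSCM and 87.3 ± 5.27 in 2iLIF against 21.0 ± 4.23 in ES. Against the list, Psmb10 was lower in EPSCM than in ES at -1.92 ± 0.13, and Tapbp lower in EPSCM than in 2iLIF at -0.62 ± 0.07, under the fold limit.

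The 5 tested genes placed on the Y chromosome were lower in ES than in 2iLIF by folds of mean FPKM from 6.05 to 9.92, for example Eif2s3y at 2.95 ± 1.09 against 28.9 ± 10.1 FPKM and Uba1y at 0.818 ± 0.0928 against 8.12 ± 0.129. A difference between the sets of libraries is argued against: the median difference was at least 2.29 in both the close libraries and those that stand apart. For EPSCM over ES the folds ran from 3.36 for Uty to 97.6 for Kdm5d, which is near 0 in ES. A loss of the Y chromosome from ES cells as the whole cause is argued against there: among the 3 genes with at least 0.5 FPKM in ES, the largest fold was at least 4.50 times the smallest in both library sets, and Uba1y was 3.02 times as high in EPSCM as in 2iLIF. For 2iLIF against ES alone, a loss of the Y chromosome from most cells of the ES cultures may account for the difference, a hypothesis found from these values: it needs similar folds for all Y-linked genes, and the largest fold was 1.64 times the smallest. By library set, these folds ran from 5.24 (Uty) to 11.1 (Uba1y) in the libraries that stand apart, 1 per medium. In the close libraries they ran from 6.28 (Uty) to 9.71 (Eif2s3y). The folds of Kdm5d rest on 0.0327 ± 0.0105 FPKM in ES. EPSCM over 2iLIF gave folds of 12.7 for Kdm5d (3.19 ± 0.639 against 0.251 ± 0.0762 FPKM) and 3.02 for Uba1y. Those of Eif2s3y, Ddx3y and Uty were 1.03, 0.720 and 0.556. Such unequal folds argue against a loss of the whole Y chromosome as the only cause of the difference between these 2 media. A response of single Y-linked genes to the medium stays open, as untested.

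Genes of chromosome 1 lay lower in both EPSCM and 2iLIF than in ES (medians -0.29 and -0.28), and on chromosome 14 block 9 of 10 consecutive blocks of genes had a median of -1.06 and block 10 of 0.77 for EPSCM against ES. Expression level, transcript length and GC content are argued against. After they were fitted out, the range of block medians on chromosome 14 was still 0.977 of its size. The chromosome 1 shift was at least 1.02 of its size in both comparisons. A change of copy number, a hypothesis found from these values, may be behind both. 10 of 10 blocks of chromosome 1 had a median below that of the other autosomes in both comparisons. This rule was written after the shift had been seen. The blocks were uneven, from 0.04 to -0.47 for EPSCM against ES and from -0.05 to -0.48 for 2iLIF against ES. On chromosome 14 the range of block medians was 1.83. All 10000 draws of as many genes from all autosomes gave a smaller range (permutation p = 0.0001, the smallest they can give). The draws treat genes as independent, so they cannot tell a change of copy number from regulation of neighbouring genes. A test would be a count of the chromosomes or a DNA profile of these cultures, not analysed here. Regulation by the medium of many neighbouring genes stays open, as untested.

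In the libraries that stand apart, 7738 of 12330 genes differed from the close libraries at a limma adjusted p under 0.05, and 61 of them by at least 1 on the log2 scale, 56 lower and 5 higher. The largest of these falls were in small RNA genes, with Mir8094 at -4.29, Snora64 at -3.46 and Snora7a at -3.10. Usmg5, Med21 and Uqcrb were also among the lower. Some small RNA genes were higher without passing, such as Snora17 at 1.42. The shifts correlated across genes between every pair of media, at r = 0.713 or more. These libraries were picked by their common place on the third component of the same values. The counts of genes therefore describe a picked split and do not test whether these libraries differ. For the same reason this correlation cannot test separate changes in each culture. A bias with GC content between library preparations is a candidate explanation: Spearman's rho between a gene's shift and the GC content of its transcript was 0.693, with a median shift of -0.27 among the genes with the lowest GC content and 0.16 among those with the highest. Transcript length alone is left undecided, with rho = -0.137. The labels give no date or batch, and no biological explanation was tested, since each medium holds 1 such library.

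Whether chance can be excluded was asked with other splits of the libraries. For each pair of media the 6 libraries make 10 splits, too few for a share under 0.05. The real split called 2423 genes in EPSCM against ES, 1979 in EPSCM against 2iLIF and 1817 in 2iLIF against ES, each reached by 1 split, the real one, and the highest other splits called 2, 1 and 1. For lists called by camera the real splits gave 12, 7 and 11, the highest others 9, 8 and 10, and 1, 3 and 1 of the 10 splits reached as many. Over 100 drawn splits of the 9 libraries, only the real split reached the 10544 genes that differ among the media (highest other 4236). The 603 genes higher in EPSCM than in both were reached by 2 of 100 (highest other 756), and the 236 lower by 4 of 100 (highest other 528). The 788 genes shared by the comparisons against ES were reached by 5 of 100, the limit set beforehand, with a highest other of 1129. These shares cannot exclude chance, in the grouping of the libraries or between cultures, since splits that mix the media have low counts by construction. Splits that mix all media call few genes, since mixing widens the spread within groups, and 11 of the 100 splits kept 1 medium whole. All other splits with as many genes kept the 3 libraries of 1 medium together, and splits that broke up every medium shared at most 1 gene in that overlap.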
